A study of Mus musculus with 10 samples.

How the data were processed

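Poly(A) RNA was isolated from bulk lung tissue that had been frozen, after RNA extraction with a QIAGEN RNeasy kit, and libraries were made with a directional NEBNext Ultra II kit, per the labels' protocols. The authors deposited raw read counts per gene, 1 table for each of 10 libraries, with 55421 mouse Ensembl gene IDs in each and no rows without a gene. STAR 2.6.1a is named in the submitters' processing notes. Those notes also name a human genome build, although the gene IDs are those of mouse. The counting tool, the annotation release and the strand setting are not given in the sources used here, so reads of overlapping or antisense genes may not be separated, and genes with near-identical copies may share or lose reads. Groups and replicate numbers came from the sample titles.

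Gene symbols were matched by gene ID for 55154 genes, and the 267 without a symbol, which hold 0.0213% of counts, kept their ID. Positions, transcript lengths and GC content came from GENCODE M21 on GRCm38, where 55240 of the IDs were found. A gene's length is that of its longest annotated transcript.

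The main test was edgeR 4.0.16 in R 4.3.3, with filterByExpr, TMM normalization, estimateDisp, glmQLFit and glmQLFTest at default settings, on the group alone, two-sided, with Benjamini-Hochberg adjustment over the 12321 genes that passed the filter (99.4% of counts) and a threshold of 0.05. Fold changes are KPdSPHK1 over KP. CPM values are scaled by TMM factors, and log2 CPM has a prior count of 2. Gene lists for lung cell types, tumour pathways, inflammation and sphingolipids, 43 in all, were fixed before the data were examined, as were the tests and all alternatives except those named as chosen later. The 39 lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation, with which 0 of the 9 calls held. The 4 lists with fewer tested members, those of mast cells and granulocytes, skeletal muscle, thymus and squamous epithelium, were not tested. Members of a list were also adjusted over the list alone. A list score is the mean log2 CPM of its members relative to the mean over all libraries. Single values per library were compared by exact permutation over all 252 assignments, two-sided, where the smallest possible p is 0.00794.

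Genes were named by a rule set before the data were examined. It took Sphk1, Sphk2, Kras and Trp53, up to 12 genes in each direction with the smallest p among those past the threshold with a mean of at least 1 CPM, filled to 6 where fewer passed, leaving out immunoglobulin and T cell receptor segments, pseudogenes and predicted genes, and the 4 tested members of each list with the smallest p, of which the text gives up to 4 per list, and for some lists none. Gm42418 and Malat1 fall outside the rule and were named after their values were seen.

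The alternatives were DESeq2 size factors and upper-quartile normalization in edgeR, no filter on low counts, a filter of 1 CPM in 5 libraries, a robust quasi-likelihood fit, the replicate number as a block, each library left out in turn, a covariate of Y-linked over Xist counts, DESeq2 1.42.0, limma-voom with quality weights, other thresholds and the fry list test. Chosen after the data were seen were a correction for transcript length and GC content (a smooth trend of each library's log2 CPM deviations, fitted with mgcv 1.9.3 and used as an offset), the same correction with the replicate block, each library's length slope as a covariate, and exact permutation of list scores.

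On simulated counts with the real means and library sizes, over 12321 genes of the KPdSPHK1 against KP comparison, the main test recovered 3 of 67 genes changed 1.5-fold, 22 of 67 changed 2-fold and 58 of 66 changed 4-fold, with 6 false calls. With a simulated length trend alone, the correction took the Spearman rho of fold change on length from -0.654 to -0.027. All 20 pairs of libraries within a group differed by far more than sampling noise (chi-square per degree of freedom of 6.08 to 56.2). Each library was counted as its own replicate. Separately prepared libraries of the same animal could differ as much, so this check does not show that each came from a separate animal. Figures were drawn with matplotlib.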

Results

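Bulk lung tissue from mice carrying lung tumours was profiled by poly(A)-selected RNA sequencing, in 5 libraries labelled KP and 5 labelled KPdSPHK1. Tumours had been induced 14 weeks before the organs were taken. KP is the usual name of a mouse lung adenocarcinoma model that combines mutant Kras with loss of the tumour suppressor Trp53, although the labels do not spell it out. KPdSPHK1 was taken as the same model with loss of Sphk1, which encodes sphingosine kinase 1, an enzyme that makes the signalling lipid sphingosine 1-phosphate. The comparison asks how the transcriptome of the tumour-bearing lung, its inflammatory genes included, differs when Sphk1 is lost. Total counts per library ran from 2523434 to 4730354, with a mean of 3706590 ± 744532 (SD, n = 5) in KP and 3015940 ± 468638 (SD, n = 5) in KPdSPHK1, a difference within the spread of the libraries (exact permutation p = 0.127, two-sided). The labels do not say that each library came from a separate animal, so all p-values measure the spread between these libraries, part of which may be technical.

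Sphk1 (ENSMUSG00000061878.15, chromosome 11, 116530925 to 116536674, plus strand, GRCm38) was detected in every library of both groups. It reached 9.29 ± 3.77 CPM (SD, n = 5) in KP and 6.58 ± 1.49 CPM (SD, n = 5) in KPdSPHK1, on 11 to 48 counts per library. The KP libraries held 5.54, 5.29, 9.87, 13.5 and 12.2 CPM in order of replicate number, and the KPdSPHK1 libraries 7.45, 7.37, 3.96, 6.76 and 7.34 CPM. The log2 fold change was -0.49 (SE 0.33) and did not pass the test (edgeR adjusted p = 0.323, and exact permutation p = 0.230 on log2 CPM). With the dependence on transcript length described below removed, an alternative chosen after the data were seen, it was -0.11 (adjusted p = 0.881). The ranges of the groups overlapped, and the labels give neither the deleted part of the gene nor the cells that lost it. Its paralogue Sphk2 had a log2 fold change of -0.31 (SE 0.22, adjusted p = 0.342; -0.02 with that dependence removed), Kras of -0.30 (SE 0.20, adjusted p = 0.312) and Trp53 of -0.90 (SE 0.39, adjusted p = 0.144). Trp53 itself was counted at 6.98 ± 2.55 CPM (SD, n = 5) in KP and 3.66 ± 1.93 CPM (SD, n = 5) in KPdSPHK1. It passed without KPdSPHK1 replicate 4 (-1.22, edgeR adjusted p = 0.0333) and with limma-voom (-1.31, adjusted p = 0.0275), and had -0.20 with each library's length slope as a covariate. Without KP replicate 4 the log2 fold change was -0.16 for Kras and -0.31 for Sphk1, and without KPdSPHK1 replicate 4 it was -0.50 for Sphk2.

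**Figure D1:**
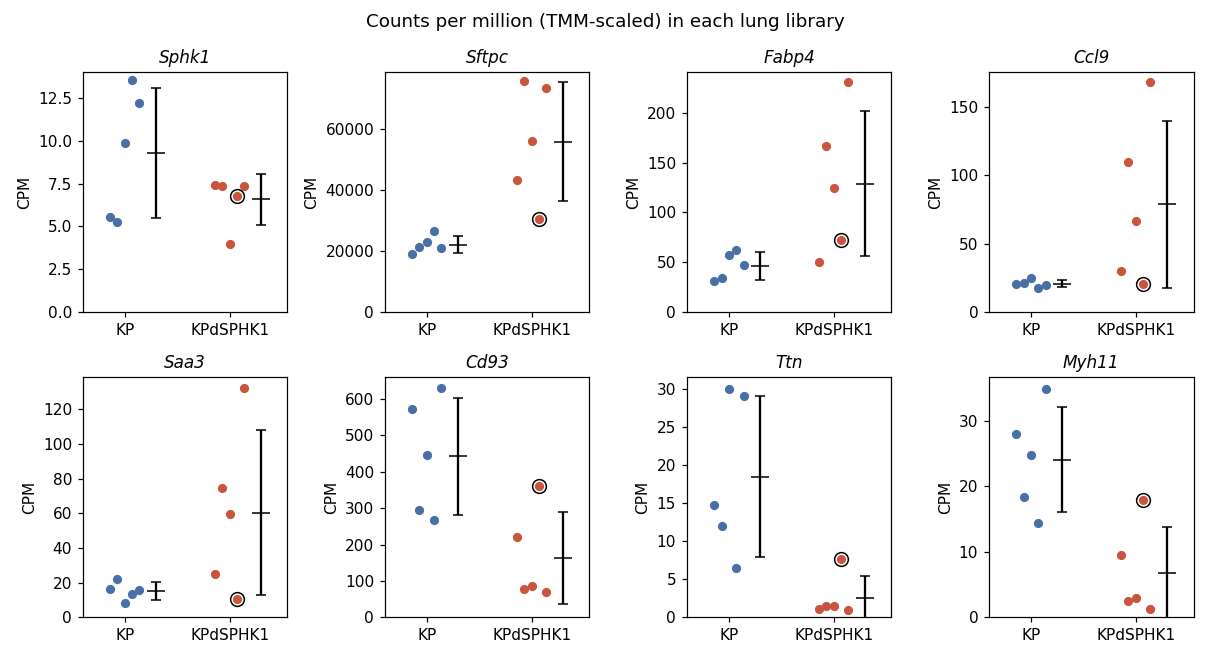
CPM (library-scaled counts, linear axis from 0) of 8 genes in each library, with blue points for KP, red points for KPdSPHK1, and black bars for the mean ± SD of 5 libraries (bars that would pass below 0 stop at 0). The ringed point is KPdSPHK1 replicate 4, which holds 361.7 CPM of Cd93 and 17.9 CPM of Myh11, inside the KP range of both genes, and 30416 CPM of Sftpc, above all KP libraries.

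Across the transcriptome, KPdSPHK1 lungs held more transcript of the surfactant gene Sftpc, of the macrophage genes Fabp4 and Mmp12 and of the chemokine Ccl9, and less of the endothelial gene Cd93, the smooth muscle myosin Myh11 and the sarcomere gene Ttn. None of these differences passed the test over all genes. Of 12321 genes tested, edgeR's quasi-likelihood test called 0 higher and 0 lower at the adjusted p threshold of 0.05, and the smallest adjusted p was 0.0706, shared by 279 genes. At an unadjusted p under 0.05 it listed 3642 genes, 1888 higher and 1754 lower, where chance alone gives 616 on average. Genes do not vary independently, so chance can give counts far from that mean. Another split of the same libraries gave 5520, and a simulated length trend with no changed gene gave 1534. The simulated spread between libraries was estimated from the real counts with their own length trend, so 1534 may be too low. DESeq2 called 1042 genes higher and 598 lower, and limma-voom with quality weights 1607 higher and 1795 lower. The groups did not overlap in 379 genes, or 3.08% of those tested, against a chance mean of 0.794%. The count of 0 moved with several choices. Without KPdSPHK1 replicate 4, edgeR called 1749 genes higher and 1858 lower. It called 735 and 567 without a filter on low counts, and 554 and 340 with a covariate of sex-linked counts. KP replicate 4 held counts of both Xist and Y-linked genes and is counted as 1 of the 5 KP libraries. Without it edgeR called 0 genes higher and 1 lower.

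The 6 genes with the smallest p in the higher direction were each above every KP library in 5 of 5 KPdSPHK1 libraries, and each had an adjusted p of 0.0706. They included Tlr7, an endosomal receptor for single-stranded RNA, at 25.2 ± 6.87 CPM against 9.39 ± 1.52 (SD, n = 5 each; log2 fold change 1.41, SE 0.23), and Irak2, a kinase of Toll-like receptor signalling, at 118 ± 35.7 against 52.7 ± 6.43 CPM (1.16, SE 0.22). The others were Comt (catechol O-methyltransferase, log2 fold change 1.29), Lipf (gastric lipase, 2.12, at a mean of 6.34 CPM), Arl11 (1.27) and Gngt2 (1.20). In the lower direction stood Lmtk2 (log2 fold change -1.69, SE 0.26), L3mbtl3 (-1.33), Zbtb16, a zinc finger transcription factor (-2.23), Hspb1, a small heat shock protein (-2.01), Plekhg2 (-1.29) and Ttn, the giant sarcomere protein titin (-2.78, SE 0.56), again all with an adjusted p of 0.0706. Hspb1 varied widely within KP, at 106 ± 64.5 CPM against 26.0 ± 8.40 CPM in KPdSPHK1 (SD, n = 5 each). With the length and GC trend removed Lmtk2 came to -1.05, Plekhg2 to -0.71 and Ttn to -1.73.

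Marker lists in bulk tumour-bearing lung describe transcript levels and not cell numbers, and cannot tell transcripts of normal cells from those of tumour cells. Alveolar type 2 cell markers, genes of the surfactant-making cells of the alveolus, were higher as a list (camera adjusted p = 0.0174, median log2 fold change 0.24), a call lost with an estimated correlation (adjusted p = 0.837). Of 24 members tested, 15 had a positive and 9 a negative fold change, 0 passed over all genes and 6, all positive, passed when adjusted over the list alone. Sftpc, surfactant protein C, stood at 55690 ± 19406 CPM against 22112 ± 2713 (SD, n = 5 each; log2 fold change 1.33, SE 0.30), and Rnase4 (1.09), Cxcl15 (1.03) and Sftpd (0.89) were likewise above every KP library in 5 of 5 KPdSPHK1 libraries. Removal of the length and GC trend took Sftpc to 0.76, Rnase4 to 0.60 and Cxcl15 to 0.58. The list's call was lost with the sex-linked covariate (adjusted p = 0.0746) and without KPdSPHK1 replicate 4 or KP replicate 4 (up to 0.0862).

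The alveolar and the tumour-associated macrophage lists were higher in KPdSPHK1 at the preset correlation, and both calls were lost with an estimated correlation (adjusted p = 0.837). Monocyte and interstitial macrophage markers were not called (21 tested, 13 positive and 8 negative, median log2 fold change 0.08, camera adjusted p = 0.725). Of 19 alveolar macrophage markers, 10 passed when adjusted over the list alone, all positive, and 0 over all genes (camera adjusted p = 0.00190, median log2 fold change 0.70). Fabp4, a lipid-binding protein, had a log2 fold change of 1.48 (SE 0.36), the chitinase-like Chil3 1.43 (SE 0.37), the lectin receptor Siglecf 1.00 (SE 0.27) and the proton pump subunit Atp6v0d2 0.91 (SE 0.22). Of 18 tumour-associated macrophage markers, 8 passed when adjusted over the list alone, all positive, and 0 over all genes (camera adjusted p = 0.00243, median 0.72), with Mmp12, macrophage elastase, at 1.68 (SE 0.41), Fabp5 at 0.97, Cd9 at 0.96 and the lipid receptor Trem2 at 1.17. Of 11 MHC class II genes, which present antigen to helper T cells, 2 passed when adjusted over the list alone and 0 over all genes (camera adjusted p = 0.0455, median 0.38), with H2-DMb2 at 0.90, H2-DMb1 at 0.91, H2-Ab1 at 0.56 and H2-Aa at 0.54. With an estimated correlation its adjusted p was 0.840. With the dependence on transcript length and GC content removed, the tumour-associated macrophage list had an adjusted p of 0.00282 (0.570 with an estimated correlation), while the alveolar macrophage list came to 0.0514 (0.0178 with the replicate block added) and MHC class II to 0.134. The median log2 fold changes of these lists then were 0.39, 0.13 and 0.25, in that order. Single members then came closer to 0, Cd9 to 0.38, Chil3 to 0.90, Atp6v0d2 to 0.58, H2-DMb2 and H2-DMb1 to 0.60 and H2-Ab1 to 0.28. The MHC class II call was also lost with the sex-linked covariate (adjusted p = 0.103) and on leaving out KP replicate 1, 3, 4 or 5 or KPdSPHK1 replicate 4 or 5 (up to 0.149).

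The endothelial, heart muscle and smooth muscle lists were lower at the preset correlation. With an estimated correlation these calls were lost, at an adjusted p of 0.840 for the endothelial and 0.837 for both muscle lists. Of 25 endothelial markers, 20 had a negative fold change and 14 of these an unadjusted p under 0.05, yet 0 passed over all genes or when adjusted over the list alone (camera adjusted p = 0.000111, median log2 fold change -0.83). Cd93, an endothelial surface receptor, stood at 164 ± 127 CPM against 442 ± 161 (SD, n = 5 each; log2 fold change -1.43, SE 0.43), with Lyve1 at -1.34, the von Willebrand factor gene Vwf at -0.98 and the transcription factor gene Sox18 at -1.44. All 11 heart muscle markers had a negative fold change, 5 passing when adjusted over the list alone and 0 over all genes (camera adjusted p = 0.000111, median -0.93). Among them were Ttn, the cardiac actin Actc1 (-1.46), Tnnc1 (-1.36) and Tnnt2 (-1.38). Of 14 smooth muscle and pericyte markers, 13 were negative, and 3 negative and 1 positive passed when adjusted over the list alone, with 0 over all genes (camera adjusted p = 0.00332, median -0.83). Myh11 had a log2 fold change of -1.76 (SE 0.51), the proteoglycan gene Cspg4 -0.99 and calponin Cnn1 -1.53, whereas the pericyte gene Higd1b had 1.24. The trend's removal took Vwf to -0.27, Cspg4 to -0.24 and Higd1b to 0.54. KPdSPHK1 replicate 4 lay inside the KP range of all these scores, at 0.78 for heart muscle where the other KPdSPHK1 libraries lay between -1.43 and -0.43.

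Ciliated and alveolar type 1 cell lists were lower at the preset correlation, and both calls were lost with an estimated correlation (adjusted p = 0.840). Of 21 ciliated cell markers, 20 had a negative fold change and 0 passed over all genes or when adjusted over the list alone (camera adjusted p = 0.0289, median -0.39), with the dynein heavy chain Dnah9 at -1.09, Hydin at -1.08, the ciliogenesis regulator Foxj1 at -0.73 and Drc1 at -0.81. Of 18 alveolar type 1 markers, genes of the flat gas-exchange cells, 15 were negative, 1 passed when adjusted over the list alone and 0 over all genes (camera adjusted p = 0.0462, median -0.27). That was the basement membrane collagen Col4a3 (-1.33, SE 0.30), followed by Pxdc1 (-0.68), Akap5 (-0.82) and Sec14l3 (-0.96). With the length and GC trend removed Dnah9 came to -0.33, Hydin to -0.36, Col4a3 to -0.77 and Akap5 to -0.52. Both calls were lost with the sex-linked covariate (adjusted p = 0.0746). The ciliated call was lost on leaving out any of 3 libraries (KP replicates 1 and 5 and KPdSPHK1 replicate 3, adjusted p up to 0.144) and the alveolar type 1 call on leaving out any of 5 (those 3 and KPdSPHK1 replicates 1 and 2, up to 0.166).

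**Figure D2:**
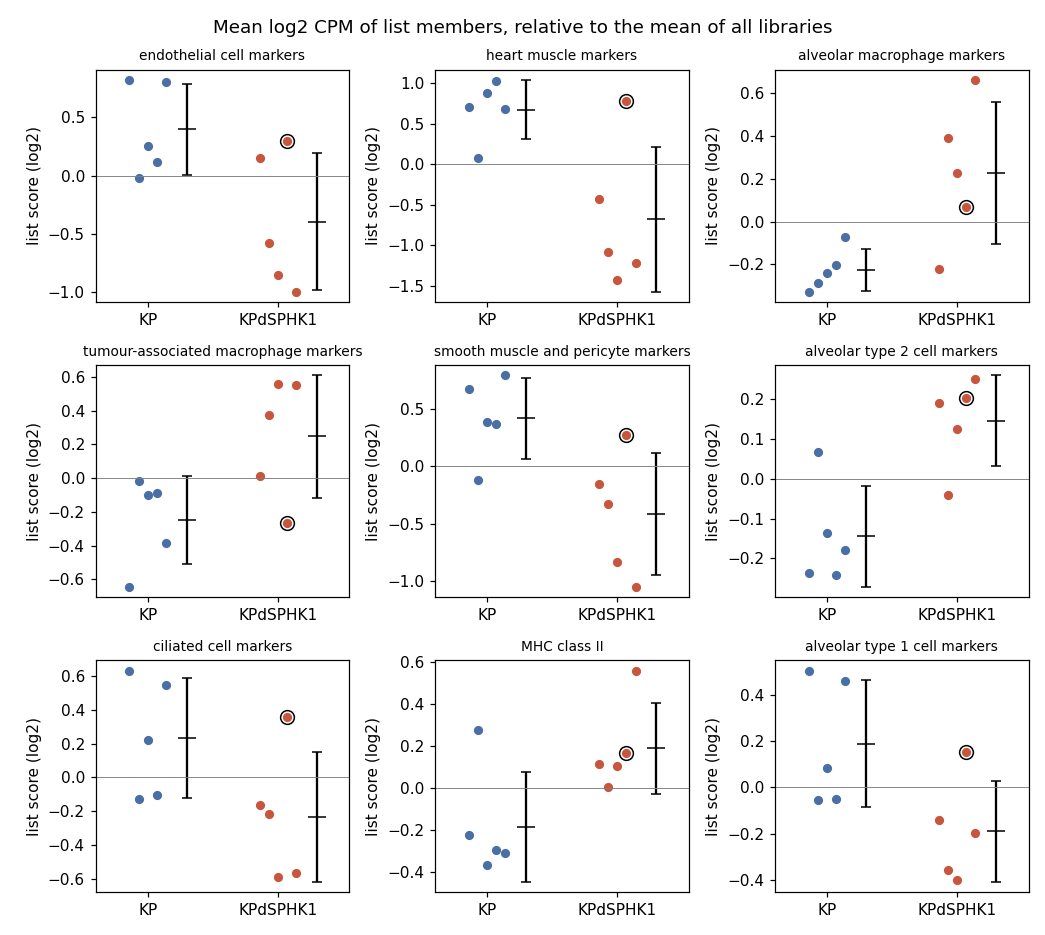
Mean log2 CPM of the members of each of the 9 lists past the camera threshold, relative to the mean of all libraries, with blue points for KP, red points for KPdSPHK1 and black bars for the mean ± SD of 5 libraries. The ringed point is KPdSPHK1 replicate 4, which lies with the KP libraries for endothelial (0.30) and heart muscle markers (0.78) and above all of them for alveolar macrophage (0.07) and alveolar type 2 markers (0.20).

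Inflammatory genes did not pass as lists in the main test. Of 62 cytokine and chemokine genes 30 were tested, and 5, all positive, passed when adjusted over the list alone, with 0 over all genes (camera adjusted p = 0.0771, median 0.26). With the length and GC trend removed, the median of this list was -0.01 (adjusted p = 0.822), whereas 5 of 24 alternatives called it higher: no filter on low counts, the filter of 1 CPM, the replicate block, and leaving out KP replicate 1 or KPdSPHK1 replicate 3 (lowest adjusted p = 0.0109). Its camera adjusted p with an estimated correlation was 0.840, and 0.927 with the trend also removed. The macrophage chemokines Ccl9 and Ccl6 had log2 fold changes of 1.92 (SE 0.44) and 1.39 (SE 0.38), Il18, an inflammasome-processed cytokine, 1.61 (SE 0.38), and Ccl17, a ligand of Ccr4, 1.81 (SE 0.55). For Ccl9 the spread was wide, at 78.8 ± 60.9 CPM against 20.7 ± 2.58 (SD, n = 5 each). Ccl17 was above every KP library in only 2 and Ccl6 in only 3 of the 5 KPdSPHK1 libraries, Ccl9 and Il18 in 4 each. The acute phase gene Saa3 stood at 60.5 ± 47.8 against 15.1 ± 5.20 CPM (1.99, SE 0.50), the member of its list of 15 that passed when adjusted over the list alone, and Serpina3g, which has close paralogues that could share its reads, had 0.95 (camera adjusted p of the list 0.375). In the NF-kB list of 23 tested genes (camera adjusted p = 0.530), Bcl2a1b, whose near-identical copies make its count uncertain, had 1.85, Cd83 0.63 and Nfkb1 -0.45. Neutrophil markers (10 tested, 6 positive and 4 negative, camera adjusted p = 0.554) ran from -0.60 to 1.24, the latter for Clec4e (adjusted p = 0.112). Their median log2 fold change was 0.19, and -0.28 with the trend removed. Removal of the trend took Il18 to 0.73, Ccl6 to 0.81, Ccl17 to 0.93 and Bcl2a1b to 0.91.

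Genes of the sphingolipid and sphingosine 1-phosphate pathway went both ways, 17 of 39 tested members positive and 22 negative (camera adjusted p = 0.969). The ceramidase Acer3 (0.93, SE 0.23) was the member that passed when adjusted over the list alone, beside Ormdl1, a regulator of sphingolipid synthesis (1.20), the galactosylceramidase Galc (0.64) and the receptor S1pr3 (-1.43). Of 23 RAS-MAPK output genes (camera adjusted p = 0.739), 3 positive and 2 negative passed when adjusted over the list alone and 0 over all genes, with the growth factor gene Ereg at 1.02, Myc at 1.00, the phosphatase gene Dusp5 at 0.70 and Etv4 at -1.14. Of 38 proliferation genes 0 passed either way (camera adjusted p = 0.375), and their examples differed in sign, Birc5 at 0.96, Stmn1 at 0.62 and Cenpa at 1.01 against Mki67 at -1.13. The p53 targets Gdf15 (0.99) and Mdm2 (0.55) and the tumour progression genes Lgals3 (0.86), Itgb4 (-1.20) and Zeb1 (-1.05) did not pass, and neither did their lists (camera adjusted p = 0.530 and 0.990). Without the length and GC trend Acer3 had 1.42, Mki67 -0.58, Stmn1 0.13 and Itgb4 -0.55.

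Fold change followed transcript length across genes. Over 12317 genes with a length, which are not independent replicates, the Spearman rho of log2 fold change on the length of the longest annotated transcript was -0.518, and -0.046 after removal of the length and GC trend of each library. The median log2 fold change went from 0.61 among the 1234 genes with the shortest transcripts (69 to 1371 bases) to -0.53 among the 1231 with the longest (6842 bases and more). Each library's slope on length was 0.153 ± 0.10 (SD, n = 5) in KP and -0.153 ± 0.185 (SD, n = 5) in KPdSPHK1 (exact permutation p = 0.0238), where KPdSPHK1 replicate 4 had 0.154. Ribosomal protein genes, which have short transcripts, took 3.99% ± 1.08 of counts in KP and 7.20% ± 2.5 in KPdSPHK1 (SD, n = 5 each; exact permutation p = 0.0317), and the predicted gene Gm42418 took 8.21% ± 1.25 and 4.82% ± 2.44 (exact permutation p = 0.0238). Malat1, a nuclear long noncoding RNA, had a log2 CPM of 11.79 ± 0.66 in KP and 10.40 ± 0.75 in KPdSPHK1 (SD, n = 5 each; exact permutation p = 0.0238). With the trend removed edgeR again called 0 genes higher and 0 lower, with 2628 at an unadjusted p under 0.05. Of 96 named genes 36 then moved by over 1.5 times, 33 of them closer to 0. With each library's slope as a covariate, also chosen after the data were seen, edgeR called 0 genes higher and 0 lower. Only 229 genes then had an unadjusted p under 0.05. This covariate moves with the group, so it cannot separate trend from group. With it, 3 of the 9 list calls stayed (alveolar macrophage, MHC class II and alveolar type 2). The tumour-associated macrophage, endothelial, smooth muscle, heart muscle, ciliated and alveolar type 1 calls were lost.

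**Figure D3:**
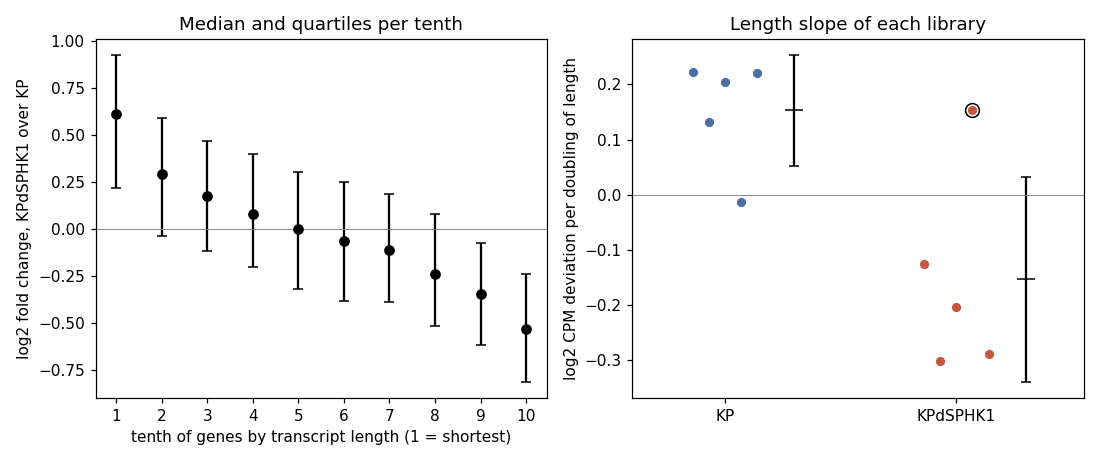
Left, median log2 fold change (KPdSPHK1 over KP) with quartiles for the genes in each decile of transcript length, from 0.61 in the shortest to -0.53 in the longest. Right, the slope of each library's log2 CPM deviation on log2 transcript length, with blue points for KP, red points for KPdSPHK1, black bars for the mean ± SD of 5 libraries and a ring around KPdSPHK1 replicate 4 (0.154).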

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

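The tests of genotype against the length trend, of all lists against the trend, and of a wrong label or a swap for KPdSPHK1 replicate 4 were chosen only after the result was seen.

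The first pattern is the dependence of fold change on transcript length. It was also present among genes of the same cell type or process, with a median rho of -0.338 over the lists of at least 10 members. The rho ran from -0.775 for T cell to -0.024 for B cell markers, with -0.079 for alveolar macrophage and -0.14 for endothelial markers. The median is what was predicted for a bias of RNA or library that acts on all genes alike. A difference with genotype that follows transcript length would give it too, so it cannot tell them apart. Library size stays open too. The rho was -0.527 with all libraries thinned to the smallest total, but random thinning hardly changes expected fold changes. It therefore could not decide on library size or on causes that go with it. Genotype stays open: the slopes differed between the groups (exact permutation p = 0.0238), yet KPdSPHK1 replicate 4 lay inside the KP range. No batch, RNA integrity value or date is in the labels, so RNA quality and genotype cannot be told apart for this trend.

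The next pattern is the lists themselves. With the length and GC trend removed, 5 of the 5 lower lists and 2 of the 4 higher lists stayed past the camera threshold at the preset correlation. That test called at least 9 lists in 44 of 100 splits of the libraries. Staying past it therefore cannot decide whether the trend is their whole cause. The medians went from -0.93 to -1.23 for heart muscle, -0.83 to -0.55 for endothelial, -0.83 to -0.53 for smooth muscle, -0.39 to -0.54 for ciliated, -0.27 to -0.34 for alveolar type 1, 0.72 to 0.39 for tumour-associated macrophage and 0.24 to 0.18 for alveolar type 2 markers. None of these calls held with an estimated correlation, either before or after the removal (adjusted p of 0.570 to 0.663 after it, exact permutation p of the scores 0.0317 to 0.0794 unadjusted), and the length slope covariate, which ended the 5 lower calls and that of tumour-associated macrophages, moves with the group and cannot separate trend from group. For alveolar macrophage and MHC class II genes 0 lists stayed, although the former passed with the replicate block added to the correction (adjusted p = 0.0178). Their medians went from 0.70 and 0.38 to 0.13 and 0.25. The trend stays open, since their score differences went from 0.45 and 0.37 (exact permutation p = 0.0238 and 0.0397) to 0.26 and 0.25 (0.111 and 0.127). A smaller share of every cell type other than macrophages and alveolar type 2 cells was predicted to lower endothelial and fibroblast genes alike. This holds only if no other change raises the genes of the fibroblast and matrix list, which was not tested. With the trend removed, the endothelial score differed by -0.70 (exact permutation p = 0.0714) and the fibroblast score by 0.04 (0.794). The endothelial minus fibroblast score differed by -0.75 (exact permutation p = 0.0556), short of the threshold of 0.05, which leaves this open.

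The last pattern is KPdSPHK1 replicate 4. On an axis from the KP mean at -1 to the KPdSPHK1 mean at 1, from which each library was left out in turn, it lay at -0.94, and at -0.88 with the length and GC trend removed, which argues against that trend as the cause. A wrong label stays open, as its 6.76 CPM of Sphk1 lies inside the ranges of both groups. In the direction of its label it lay above every KP library for Sftpc (30416 CPM) and the scores of alveolar type 2 (0.20, KP up to 0.07) and alveolar macrophage markers (0.07, KP up to -0.07). These were picked with it counted as KPdSPHK1, so they are no independent evidence for its label. For every other called list its score lay inside the KP range, including tumour-associated macrophage (-0.26, KP -0.64 to -0.02) and MHC class II (0.16, KP up to 0.27). A swap with KP replicate 4, which lay at 0.11 and at -0.002 with the trend removed, could not be decided. The grouping after such a swap gave 2039 genes higher and 2115 lower in edgeR, where the labels as given had 0 and 0. It was the highest of the splits described below, and libraries that lie apart for another reason would give it too. Against a swap, the 13.5 CPM of Sphk1 in KP replicate 4 lie above every KPdSPHK1 library. A true difference between animals of the same genotype was not tested.

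For the 0 higher and 0 lower genes called by edgeR (DESeq2 called 1042 and 598, and 3642 genes had an unadjusted p under 0.05), each of the 100 splits drawn from the 126 possible gives at least as many by construction, so the splits say nothing about chance for these counts. The highest of the other splits called 2115 genes in 1 direction, which points to a structure of the libraries. It set KPdSPHK1 replicate 4 with KP replicates 1, 2, 3 and 5, the grouping that a swap with KP replicate 4 would give. For the 3642 genes at an unadjusted p under 0.05, 3 of 100 splits gave as many, the real split included. That share is small, but it does not exclude chance for that count. The highest other value was 5520, from the same split. Chance is not excluded for the number of lists, since 44 of 100 splits of the libraries into 5 and 5 called at least the 9 lists of the real split, and another split called 20.

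Among 280 groups of 5 values tested, 11 held a library far from the other 4, where chance gives 14. In KPdSPHK1 replicate 4 these were Ttn (7.64 CPM, the others 0.957 to 1.47), Hydin (15.3 CPM, the others 3.90 to 4.91) and Myc (7.64 CPM, the others 14.4 to 16.2). KPdSPHK1 replicate 3 held 3.96 CPM of Sphk1, where the others held 6.76 to 7.45. KP replicate 2 stood apart for H2-Aa (1636 CPM), Gdf15 (7.12 CPM) and the scores of MHC class II (0.27), NK and cytotoxic lymphocyte (-0.66) and adipose markers (-0.32). KP replicate 4 held 2057 CPM of mt-Nd2, where the other KP libraries held 4311 to 4774. The score of regulatory T cell and checkpoint genes was 0.53 in KPdSPHK1 replicate 5.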

How the results depend on the processing

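The length and GC correction, alone or with the replicate block, the length slope covariate and the exact permutation of list scores were chosen after the data were seen. Against the 0 genes called higher and 0 lower, no filter on low counts gave 735 and 567, the sex-linked covariate 554 and 340, DESeq2 1042 and 598, limma-voom with quality weights 1607 and 1795, and an adjusted p threshold of 0.10 1064 and 757. Leaving out 1 library gave 0 to 1749 higher and 0 to 1858 lower, the highest without KPdSPHK1 replicate 4, with 1 lower gene without KP replicate 4 and 0 in the other 8 fits. The remaining alternatives gave 0 and 0. The replicate block also gave 0 higher and 0 lower (smallest adjusted p 0.179) and called the 9 lists plus cytokines and chemokines, and as same-numbered libraries did not deviate together (correlations of -0.56 to 0.06, 0 libraries best with their own number), the numbers were not taken as pairs. Sphk1 stayed negative and uncalled in 22 of 22 alternatives (-0.65 to -0.05). The 9 lists called became 5 with the sex-linked covariate (without alveolar type 1 and 2, ciliated and MHC class II) and 0 with an estimated correlation, fry, or exact permutation with or without the correction, and 6 to 9 without 1 library. Endothelial, heart muscle, smooth muscle and both macrophage lists held in all 10 of those fits. With the length slope covariate 3 of the 9 lists stayed called and 6 were lost. Of these, endothelial (adjusted p = 0.474), ciliated (0.132) and alveolar type 1 markers (0.910) turned higher, and heart muscle, smooth muscle and tumour-associated macrophages kept their direction. Called anew were B cell markers (turned higher, 4.85e-05) and interferon gamma, immediate early and heat shock, and sex-linked genes. Of 2112 alternative values of 96 named genes, 334 passed the threshold in the same direction, 0 reversed with a call, and 19 changed sign uncalled, all with that covariate. The cause was not tested for any of these. At these totals the main test found 22 of 67 simulated 2-fold changes.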

Other observations

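Single genes stood apart in the lists of interferon gamma response, hypoxia and glycolysis, checkpoint, complement, stress and T cell genes, which were not called and had medians between -0.18 and 0.32, none of these genes past the test over all genes. Among interferon gamma response genes, the immunoproteasome subunit Psmb9 had a log2 fold change of 0.73 and Psmb10 of 0.55, in a list whose median was 0.08 (camera adjusted p = 0.554). Bnip3, a mitophagy receptor induced by hypoxia, had 1.24 and lactate dehydrogenase Ldha 0.64, with 1 of 24 hypoxia and glycolysis genes passing when adjusted over the list alone (camera adjusted p = 0.725). The co-stimulatory receptor Tnfrsf9 had 1.33 and the complement inhibitor Cd59a 1.42, each the member of its list that passed when adjusted over the list alone. Stress genes differed in sign, the chaperone Hsph1 at -1.18 and the transcription factor Atf3 at 1.07. T cell genes did too, Cd3d at 0.88 and Bcl11b at -1.22, with transcripts of 1617 and 8111 bases. With the length and GC trend removed Psmb10 came to 0.28, Bnip3 to 0.70, Cd3d to 0.58 and Bcl11b to -0.71. The camera adjusted p was 0.430 for the stress list, 0.502 for complement, 0.513 for regulatory T cell and checkpoint genes and 0.843 for T cells. Also not called were the lists of type I interferon response (0.990), plasma cell (0.990), NK and cytotoxic lymphocyte (0.759), dendritic cell (0.725), B cell (0.572), mesothelial (0.554) and adipose genes (0.538). The list test pointed higher against a negative median for type I interferon, plasma cell and dendritic cell genes, and lower against a positive median for tumour progression genes.

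Of 15 club cell markers 12 were negative and 3 positive (median -0.34, camera adjusted p = 0.339). Of 30 fibroblast and matrix genes 19 were negative and 11 positive (median -0.05, camera adjusted p = 0.375). Neither list was called. Cyp2f2, a cytochrome of club cells, had -1.08 and the secretoglobin Scgb1a1 -0.52, Col6a1 -1.09 and Col1a2 -0.66. Of 7 platelet markers tested 5 were negative and 2 positive, from -1.57 for the platelet chemokine Ppbp to 0.86. The globin Hba-a1, which shares reads with its near-identical copy, had -1.0, and mt-Nd2 -0.64. With the trend removed Scgb1a1 had -1.08, Col1a2 -0.18 and mt-Nd2 -1.22. With the length and GC trend removed, an alternative chosen after the data were seen, club cell (adjusted p = 0.00159), red cell (0.00345), mitochondrially encoded (5.19e-05) and platelet lists (0.0490) were past the camera threshold as lower and cholesterol and fatty acid synthesis (0.0189), with Cyp51 at 0.72 before correction, as higher. All of these were lost there with an estimated correlation, at adjusted p of 0.570 or more.

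Sex-linked transcripts were mixed over both groups, with Y-linked counts in 4 of 5 KP and 2 of 5 KPdSPHK1 libraries. Xist was counted in KP replicate 3 (415 CPM) and KPdSPHK1 replicates 1, 4 and 5 (64.5, 300 and 219 CPM), where the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 counts, and 5 other libraries had Y-linked counts and 0 counts of Xist. KP replicate 4 held both, 189 counts of Xist and 519 of the Y-linked genes. It may hold RNA of a male and a female animal in the same library, in which case KP does not have 5 single animals, a hypothesis formed and tested after the counts were seen. Its 146 CPM of Y-linked genes lay below the 162 to 262 CPM of the 5 other libraries that had any, but not far enough below for a single library to decide. A small share of female RNA would lower the Y-linked level little, so this test could not detect it. Without KP replicate 4, edgeR called 0 genes higher and 1 lower, and the alveolar type 2 and MHC class II lists lost their call.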
